A study of Arabidopsis thaliana with 12 samples.

How the data were processed

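The arrays measured transcript levels in rosettes of Arabidopsis thaliana in a factorial design of wounding and light, with 4 groups of 3 arrays: intact and wounded rosettes in the light, and intact and wounded rosettes in the dark. Plants were kept at 22 °C for 30 min, were crushed with a haemostat or left intact, in the dark under a safelight, and were collected 60 min later, per the sample descriptions. For dark wounded replicate 2 the treatment text is only an abbreviation, and that array was placed by its title and source name. Each array took 1 extract of total RNA from 15 to 17 pooled plants, labelled with biotin.

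Per the submitters' processing notes the values were made with GCRMA, with no version given. The deposited values of the authors are on the log2 scale: they run from 1.46 to 15.85, with medians between 5.40 and 5.60 on every array, and no value is missing. The table has 22810 probe sets, of which 64 are Affymetrix controls. It holds no detection calls, so a probe set was tested when its log2 value was at least 4 on at least 3 of the 12 arrays, which left 13567 and set aside 9179 dim ones. Depth does not apply to these arrays, and their number limits the precision: the median SE of a change was 0.21, and that of the interaction 0.29.

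The annotation gave 1 gene to 13513 probe sets, several genes to 503 and none to 8730 (7275, 292 and 6000 of those tested). Genes are named only where the annotation gives a probe set a single gene, and probe sets with no named gene enter the counts alone. A gene with several probe sets is represented by the one with the highest mean. Symbols were matched to loci for 13436 probe sets, with 77 left unmatched.

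Group comparisons used limma 3.58.1 in R 4.3.3, with 1 mean per group, all 12 arrays in the fit, empirical Bayes moderation with its default settings (residual df 8, prior df 3.19) and Benjamini-Hochberg adjustment over the 13567 probe sets of each contrast. A probe set was called at an adjusted p under 0.05, two-sided. The contrasts were wounded minus intact in the light and in the dark, light minus dark in intact and in wounded rosettes, and the interaction, which is the wound effect in the light minus that in the dark. In the contrasts of light and dark, a rise or fall means a level higher or lower in the light. No group was collected before the light or dark treatment, so a rise in the light cannot be told from a fall in the dark. The contrasts, tests, gene lists, naming rule and the alternatives not said to be added later were chosen before the data were examined. The rule for named genes takes, per contrast, the 8 largest rises and the 8 largest falls among called probe sets of 1 gene whose arrays do not overlap between the 2 groups (for the interaction, with the same sign in each experiment). It adds from each list the 3 called members with the largest change, or the 2 brightest tested members where none was called. Genes named outside this rule are said to be chosen after their values were seen.

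The 3 replicate experiments each held all 4 treatments, per the series description, and replicate numbers were checked as pairing the arrays. After removing group means, all 18 pairs of arrays with the same number had positive r (0.30 to 0.76 across probe sets, which are not independent replicates). All other pairs had negative r (-0.47 to -0.07), which follows in part from removing means of 3 arrays. The fit without a replicate term was the planned one. The SEs, named calls, 2-fold counts and overlap counts come from it unless said otherwise, and so do not use the pairing. The fit with the replicate number as a block is given beside each count of calls.

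The 27 gene lists cover jasmonate biosynthesis, JAZ repressors, jasmonate catabolism and conjugation, jasmonate signalling and response, rapid wound, touch and stress regulators, WRKY factors of stress, ethylene, salicylate, abscisate and dehydration, early auxin response, glucosinolate and tryptophan, the circadian clock, nuclear photosynthesis, chlorophyll biosynthesis, light signalling and photoprotection, flavonoids, shade and phytochrome, dark and sugar starvation, starch and sucrose, nitrate assimilation, reactive oxygen, heat shock, expansins, housekeeping, root markers, shoot apex and flower markers, and guard cell, trichome and phloem markers. Of their 376 entries (375 loci), 49 had a named probe set and 44 were tested. The JAZ, ethylene, salicylate, shade and phytochrome, nitrate, reactive oxygen, shoot apex and flower, and guard cell, trichome and phloem lists (8 in all) had no named probe set, and the 1 named heat shock probe set was too dim, so these lists were not analysed here. The 13 lists with at least 2 tested members were tested with limma's camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, each adjusted by Benjamini-Hochberg over the lists of a contrast. In addition, 32 families of genes that share a symbol stem, each with at least 5 tested members, were tested the same way, and these were chosen after the coverage of the lists was seen but before their values were.

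The procedure was tested on simulated data built from the arrays' own spread. With 100 probe sets raised or lowered by a log2 change of 1 and 100 by 2, limma recovered 54 and 96 for wounding in the light, 58 and 96 for light in wounded rosettes, and 22 and 85 for the interaction, with 3.23%, 7.23% and 5.31% false calls. Camera called a raised list, and of 100 unchanged lists it gave 3 an unadjusted p below the 0.05 threshold. The simulated spread was independent between probe sets and arrays, and the simulated lists were larger than the gene lists. These checks therefore do not cover spread shared by the arrays of an experiment, or small lists with correlated members.

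Alternatives were the replicate block, fits of the 2 groups of a contrast alone, no brightness filter or one at log2 6, quantile normalization, median centring, a trended and robust prior, array weights, an adjusted p under 0.01, a 2-fold minimum, and leaving out each array or each replicate experiment. Added after the data were seen were the 25S ribosomal RNA control value as a covariate, and the block combined with median centring, with the trended and robust prior or with the 25S value. Splits of the arrays into other groups were refitted, with 100 random assignments for the interaction. Tables and figures were made with python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.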

Results

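Transcript levels in rosettes of Arabidopsis thaliana were measured on 12 Affymetrix arrays, to ask how the light environment bears on the response to wounding. Plants stood either in light of 250 µmol of photons per square metre and second or in the dark, and were either left intact or wounded by crushing with a haemostat, which gave 4 groups. Each group had 3 arrays, from 3 replicate experiments that each held all 4 treatments, and each array carried a single RNA extract pooled from 15 to 17 plants. Rosettes were collected 60 min after wounding, or at the matching time in intact plants. Of 22810 probe sets, 13567 were bright enough to be tested, and 13107 to 13258 probe sets reached a log2 value of 4 on each array. The median log2 value of an array lay between 5.40 and 5.60. Values are log2, changes are differences between means of 3 arrays with their SE from limma, and the number of arrays limits the precision. Of the 27 gene lists chosen beforehand, with 376 entries in all, 49 entries had a named probe set and 44 were tested, so that each list is described here by the few members that could be read.

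Wounding in the light raised transcripts of rapid stress regulators and of jasmonate turnover and lowered an expansin. AT1G22810, a transcription factor of the ERF family, rose by 7.16 ± 0.79 on the log2 scale, from 2.57 ± 0.50 in intact to 9.74 ± 0.25 in wounded rosettes (SD, n = 3). This is at least 53.4-fold when the intact level is set to the brightness threshold of log2 4. AT4G27654 rose by 6.81 ± 0.22 (at least 67.6-fold on the same footing) and AT5G52050, the efflux carrier DTX50, by 6.45 ± 0.42 (at least 49.9-fold). The other 5 of the 8 largest rises among named genes were AT3G53600, a C2H2 zinc finger protein (5.74), AT2G14290 (5.66), AT5G12340 (5.54), AT1G19210, another ERF family factor (5.40), and AT5G38700 (5.34). The largest fall was that of EXPA8, an expansin that loosens cell walls, which was 10.6-fold lower (log2 change -3.40 ± 0.43). AT3G17640 (-2.96), AT3G23880 (-2.82), AT3G62550 (-2.59), AT2G39920 (-2.37), AT1G11700 (-2.33), AT5G11930 (-2.25) and AT5G47610 (-2.2) followed. By the naming rule, the wounded and intact arrays did not overlap for any of these 16 genes. The lower of the 2 means was below log2 4 for 12 of them, where the size and rank of a change are those of the deposited values. The call of AT2G39920 was lost without light unwounded replicate 2 (limma adjusted p = 0.0571), light wounded replicate 1 (0.0530) or light wounded replicate 3 (0.0512).

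Of 39 listed rapid wound, touch and stress regulators, 3 were tested and all 3 rose in wounded rosettes in the light. These were the calmodulin-like proteins CML37 (log2 change 4.91 ± 0.50) and CML38 (4.27 ± 0.52) and the zinc finger repressor STZ, also called ZAT10 (2.86 ± 0.41). Their mean change lay 4.16 above the median change of all tested probe sets, which was -0.15, and the list passed limma's camera test (adjusted p = 3.13e-05), but not with an estimated correlation (adjusted p = 0.127). Among WRKY factors of stress, 2 of 3 tested rose, WRKY22 (4.28 ± 0.35) and WRKY6 (1.89 ± 0.37), and 3 passed when adjusted over the list alone (camera adjusted p = 4.34e-04, and adjusted p = 0.127 with an estimated correlation). Of 4 tested genes of jasmonate catabolism and conjugation, 2 rose, and 3 passed when adjusted over the list alone. Those that rose were the jasmonate oxidases AT2G38240 (JOX4, 3.1 ± 0.35) and AT5G05600 (JOX2, 2.31 ± 0.30), and the list passed both camera (adjusted p = 4.07e-04) and camera with an estimated correlation (adjusted p = 0.0470), though not with an estimated correlation and the replicate block together (adjusted p = 0.166). OPCL1, a ligase of jasmonate biosynthesis and the 1 tested member of that list, rose by 2.08 ± 0.47, with a limma adjusted p of 0.0120 that became 0.0524 without light wounded replicate 2. In the list of jasmonate signalling and response, 1 of 4 tested members rose, the glutaredoxin GRX480 (3.38 ± 0.48), and 1 fell, the transcription factor MYC4 (-1.32 ± 0.27), and the list did not pass (camera adjusted p = 0.583).

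Of the expansins 1 of 2 tested fell, EXPA8, and 2 passed when adjusted over the list alone (camera adjusted p = 0.0461, and adjusted p = 0.127 with an estimated correlation). Of 3 tested abscisate and dehydration genes 1 rose, the dehydrin COR47 (1.01 ± 0.20, camera adjusted p = 0.253 for the list). None of 5 tested nuclear photosynthesis genes passed, and the brightest were RCA, which encodes Rubisco activase (15.18 ± 0.03 in intact and 15.19 ± 0.06 in wounded rosettes), and PSAE-1, a subunit of photosystem I (14.95 ± 0.03 and 14.83 ± 0.04). Both stood near the highest value of all arrays, 15.85, where a change could be compressed. None passed among 3 tested genes each of chlorophyll biosynthesis, flavonoids and housekeeping, and none among 2 tested genes each of starch and sucrose, early auxin response, and glucosinolate and tryptophan, although 1 gene each of the last 2 lists passed when adjusted over the list alone. The single tested members of the circadian clock list (GI, -0.11 ± 0.25), the light signalling list (HYH, 0.10 ± 0.44), the dark and sugar starvation list (AKINBETA1, 0.01 ± 0.23) and the root marker list (PYK10, 8.47 ± 0.83 intact and 8.70 ± 0.56 wounded, SD) did not pass either. Under the replicate block 9 more listed genes passed, named here after their values were seen. PORB (-1.16 ± 0.23) and CHLM (-0.34 ± 0.10) of the chlorophyll list fell, as did LHCB4.2 (-0.39), UGT78D1 (-0.58), APL3 (-0.64), WES1 (-1.17) and EXPA4 (-0.74). JRG21 (1.35) and AT2G04400 (0.88) rose. Only UGT78D1 was lost when the arrays were also centred on their medians (limma adjusted p = 0.0577).

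In all, 2015 probe sets passed limma's test for wounding in the light at a Benjamini-Hochberg adjusted p under 0.05, 1151 higher and 864 lower, of which 894 and 346 changed at least 2-fold. The 2 groups of arrays did not overlap for 2008 of these, and over all tested probe sets they did not overlap for 37.0%, where chance gives 10%. With the replicate number as a block the count was 3699, of which 1560 were higher and 2139 lower, and it held all 2015. The excess of rises was thus not kept with the block, nor with the block and median centring joined (1600 higher and 1861 lower). Without light unwounded replicate 2 the count was 1336.

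**Figure D1:**
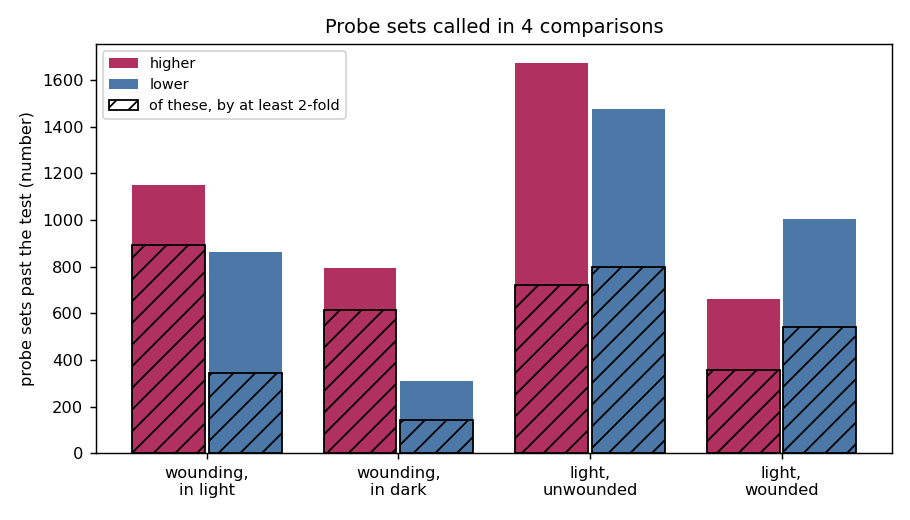
Number of probe sets past the test (limma, Benjamini-Hochberg adjusted p under 0.05, 3 arrays per group) that were higher or lower in wounded than in intact rosettes, in light and in dark, and in light than in dark, in intact and in wounded rosettes. The hatched part of each bar counts those changed at least 2-fold, from 894 rises on wounding in the light to 144 falls on wounding in the dark.

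Wounding in the dark also raised stress regulators and lowered EXPA8, and 716 of the 792 probe sets it raised were raised in the light too. AT5G52050 (DTX50) rose by 5.90 ± 0.42 on the log2 scale, from 3.25 ± 0.51 to 9.14 ± 0.69 (SD, n = 3), which is at least 35.3-fold with the intact level set to log2 4. AT4G27654 rose by 5.82 ± 0.22 (at least 39.4-fold) and AT1G22810 by 4.98 ± 0.79. AT1G22810 stood at 4.97 ± 2.2 in intact rosettes in the dark, where replicate 1 had 2.43 and replicates 2 and 3 had 6.31 and 6.17, so its rise was 7.47, 3.61 and 3.86 by experiment. AT1G19210 (4.88), AT3G53600 (4.69), AT3G02840 (4.38), AT2G14290 (4.37) and CML37 (4.37) were the other 5 of the 8 largest named rises. Intact replicate 1 was also the lowest for AT3G02840 (rises of 6.38, 3.55 and 3.21 by experiment) and CML37 (5.83, 3.94 and 3.34). EXPA8 fell most, to a level 6.03-fold lower (-2.59 ± 0.43), ahead of AT1G49200 (-2.09), AT1G78450 (-1.93), AT4G34950 (-1.86), AT3G62550 (-1.76), AT3G15570 (-1.75), AT3G19850 (-1.71) and AT1G78170 (-1.69). As the naming rule requires, the arrays of the 2 groups did not overlap for any of these 16 genes. The lower mean was below log2 4 for 6 of them. AT4G34950 lost its call without dark unwounded replicate 1, dark wounded replicate 2 or dark wounded replicate 3 (limma adjusted p between 0.0538 and 0.0801), and AT3G62550 lost its call without dark unwounded replicates 1 or 2 or dark wounded replicates 1 or 3 (between 0.0795 and 0.136).

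All 3 tested rapid wound, touch and stress regulators rose in the dark as well, CML37 by 4.37 ± 0.50, CML38 by 2.99 ± 0.52 and STZ by 2.49 ± 0.41 (camera adjusted p = 2.28e-05, and adjusted p = 0.129 with an estimated correlation). Of 4 tested genes of jasmonate catabolism and conjugation 2 rose and 3 passed when adjusted over the list alone, with AT2G38240 at 2.05 ± 0.35 and AT5G05600 at 1.81 ± 0.30 (camera adjusted p = 0.00144, and adjusted p = 0.0732 with an estimated correlation). Among the WRKY factors 1 of 3 rose, WRKY22 (1.94 ± 0.35), and 3 passed when adjusted over the list alone (camera adjusted p = 0.00497, and adjusted p = 0.236 with an estimated correlation). GRX480 rose by 3.14 ± 0.48 as 1 of 4 tested jasmonate response genes, COR47 by 0.96 ± 0.20 as 1 of 3 dehydration genes, and EXPA8 was the 1 of 2 expansins that fell, in lists that camera did not call (adjusted p = 0.454, 0.405 and 0.0764). The last became 0.0376 with the replicate block, and was 0.227 with an estimated correlation and 0.258 with both (camera, adjusted p). OPCL1 rose by 1.83 ± 0.47, a call that was lost without dark unwounded replicates 1 or 3 or dark wounded replicates 1 or 2 (limma adjusted p between 0.108 and 0.153). For all these listed genes that rose except AT2G38240, intact replicate 1 was the lowest in the dark. Rises by experiment were 4.46, 2.38 and 2.13 for CML38, 3.61, 2.07 and 1.78 for STZ, and 4.19, 2.46 and 2.78 for GRX480. They were 2.65, 1.36 and 1.8 for WRKY22, 2.66, 1.4 and 1.43 for OPCL1, and 2.07, 2.34 and 1.75 for AT2G38240. None of the tested photosynthesis, chlorophyll, flavonoid, starch and sucrose, auxin, glucosinolate and housekeeping genes passed, nor did GI, HYH, AKINBETA1 or PYK10. Adjusted over the list alone, 1 auxin gene, 1 glucosinolate gene and 2 jasmonate response genes passed. With the 25S covariate described below, CML37 kept its call (limma adjusted p = 0.0254). Those of CML38, STZ and OPCL1 were lost (limma adjusted p = 0.0702, 0.0782 and 0.0612). All calls in the jasmonate catabolism, WRKY, jasmonate response, dehydration and expansin lists were lost too. With the covariate the changes were 3.3 ± 0.79 for CML38, 2.54 ± 0.63 for STZ and 2.7 ± 0.62 for OPCL1. GRX480 stood at 3.25 and EXPA8 at -2.76. None of the changes behind the lost calls became smaller, and their SEs became larger. The block added falls of PORB (-0.96), CHLM (-0.36), APL3 (-0.58) and MYC4 (-0.84). It also added rises of JRG21 (1.27), GH3.3 (1.28) and AT2G04400 (0.85). These 7 are named after their values were seen.

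In the dark, 1102 probe sets passed the test for wounding (limma, Benjamini-Hochberg), 792 higher and 310 lower, of which 613 and 144 changed at least 2-fold. The arrays were separate for 1099 of them and for 21.4% of all tested probe sets, against 10% by chance. The replicate block gave 2043 (1232 higher and 811 lower), with all 1102 among them, and leaving out dark unwounded replicate 1 gave 663. A control probe set for 25S ribosomal RNA stood at 9.62 ± 0.95 in intact rosettes in the dark and at 7.57 ± 0.77 in wounded ones (SD, n = 3), and with its value as a covariate, a setting added after the data were seen, the count was 248 and 8 of the 24 named calls were kept. The median size of the 1102 changes was 1.32 with that covariate and 1.3 without it, all with the same sign. The median SE over all tested probe sets was 0.30 against 0.21.

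**Figure D2:**
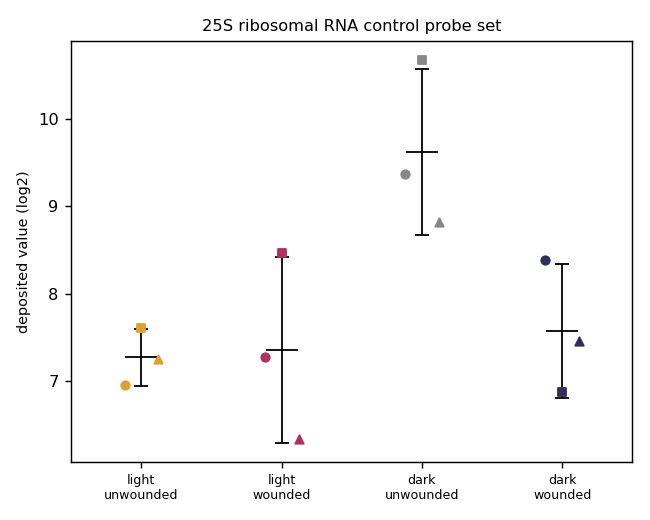
Log2 value of the 25S ribosomal RNA control probe set on each of the 12 arrays, by group, with circles, squares and triangles for replicates 1, 2 and 3 and bars for the mean ± SD. The intact dark group has its mean at 9.62 and the other groups have theirs between 7.27 and 7.57.

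In intact rosettes TBL26, of the TRICHOME BIREFRINGENCE-LIKE family of cell wall acetylation proteins, was 47.2-fold higher in the light (log2 change 5.56 ± 0.55), at 11.38 ± 0.58 against 5.82 ± 0.87 (SD, n = 3). AT2G27420 was higher by 5.36 ± 0.77 (at least 21.1-fold with the dark level of 3.03 set to log2 4), and AT5G42760 (4.70), AT2G44940, of the ERF family (4.42), AT5G01790 (4.34) and AT2G15020 (3.91) followed. AT3G52740 (3.72) and AT3G44450 (3.57), which encode the inhibitors of cryptochromes BIC1 and BIC2, completed the 8 largest named rises. Lower in the light were AT3G15630, 34.5-fold (-5.11 ± 0.48), AT3G49790, 25.3-fold (-4.66 ± 0.30), and AT2G20670, 24.3-fold (-4.60 ± 0.34). The next largest falls were those of AT1G02660 (-4.47), AT3G15450 (-4.33), AT5G19120 (-4.26), AT3G07350 (-4.13) and AT1G69890 (-4.05). Under the same naming rule, no arrays of the 2 groups overlapped for these 16 genes. Of them 3 had their lower mean below log2 4.

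**Figure D3:**
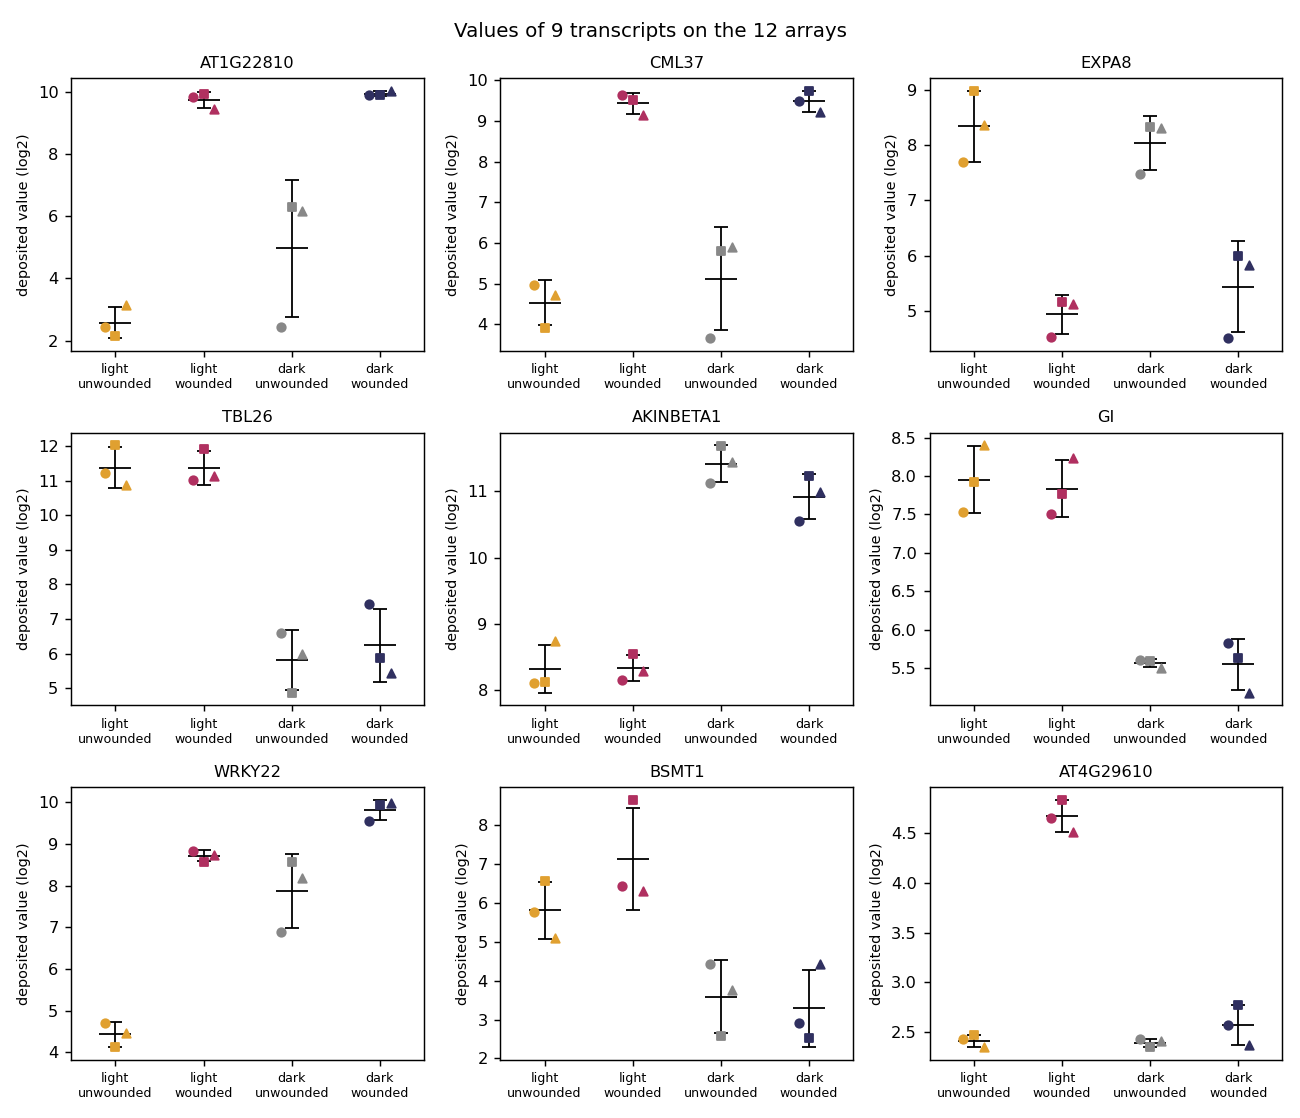
Log2 values of 9 named transcripts on the 12 arrays, by group, with circles, squares and triangles for replicates 1, 2 and 3 and bars for the mean ± SD. AT1G22810 and CML37 are high in both wounded groups, EXPA8 is low in them, TBL26 and GI are high in both light groups, AKINBETA1 is low in them, and AT4G29610 is raised in the wounded light group alone.

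Among the lists, genes of the clock, light signalling, flavonoid and dehydration lists were higher in the light in intact rosettes, and a SnRK1 subunit was lower. With no group from before the treatment, a rise or fall here means only higher or lower in the light than in the dark. GI, a clock component and the 1 tested member of its list, was 5.20-fold higher (2.38 ± 0.25, limma adjusted p = 1.10e-04). HYH, a bZIP factor of light signalling and also alone in its list, was higher by 1.74 ± 0.44. AKINBETA1, the beta subunit of the energy-sensing kinase SnRK1 and the 1 tested member of the dark and sugar starvation list, was 8.53-fold lower (-3.09 ± 0.23). Of 3 flavonoid genes 2 rose, the flavonol glycosyltransferases UGT78D1 (1.97 ± 0.28) and UGT78D2 (1.52 ± 0.28), and of 3 abscisate and dehydration genes 2 rose, COR15B (1.69 ± 0.26) and COR15A (1.29 ± 0.14). Of 3 WRKY factors 2 fell, WRKY22 (-3.45 ± 0.35) and WRKY6 (-1.50 ± 0.37), and of the 2 auxin response genes 1 fell, WES1, which conjugates auxin to amino acids (-2.02 ± 0.38), with 2 passing when adjusted over the list alone. MYC4 rose (1.56 ± 0.27) in the jasmonate response list, EXPA4 (0.81 ± 0.24) among expansins and AT2G04400 (0.85 ± 0.27) among glucosinolate and tryptophan genes, and CML38 fell (-1.70 ± 0.52) among rapid wound regulators, on arrays that overlapped between the groups. The falls of WRKY6 and CML38 were absent in experiment 1, with differences of -0.07, -2.3 and -2.13 for WRKY6 and 0.35, -2.8 and -2.66 for CML38. None of 5 photosynthesis genes, 3 chlorophyll genes, 3 housekeeping genes, 4 jasmonate catabolism genes, or 2 starch and sucrose genes passed, although 1 of the last passed when adjusted over the list alone, and OPCL1 (0.60 ± 0.47) and PYK10 did not pass. Blocking by replicate added rises of APL3 (1.49), JMT (1.01) and BCAT4 (0.87) and falls of GH3.3 (-1.04) and CHLM (-0.32). These 5 are named after their values were seen. Camera called none of the 13 lists with at least 2 tested members, and its smallest adjusted p, 0.147, was shared by the WRKY, auxin and flavonoid lists.

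Of the tested probe sets, 3147 passed for light in intact rosettes (limma, Benjamini-Hochberg), 1670 higher and 1477 lower, of which 723 and 800 changed at least 2-fold. The groups were separate for 3082 of them and for 38.2% of all tested probe sets, against 10% by chance. The count was 5516 with the replicate block (3174 higher and 2342 lower), which held all 3147. The intact dark arrays carried the high 25S control values (9.62 ± 0.95 against 7.27 ± 0.33 in intact rosettes in the light), and with the 25S value as a covariate 778 probe sets passed and 21 of the 30 named calls were kept. By list, 1 of 2 calls was kept in each of the WRKY, flavonoid and dehydration lists, MYC4, GI and AKINBETA1 kept theirs, and HYH, CML38, WES1, EXPA4 and AT2G04400 lost theirs. Among the lost calls, the change of HYH went from 1.74 to 0.77, that of UGT78D2 from 1.52 to 0.98 and that of EXPA4 from 0.81 to 0.49. CML38 stood at -1.35 with the covariate, WES1 at -1.78, WRKY6 at -1.49 and COR15B at 1.55. AT2G04400 went from 0.85 to 1.29. The 778 were fewer than for wounding in the light (1883) or light in wounded rosettes (1546). The median size of the 3147 changes was 0.98 with and without that covariate. The median SE over all tested probe sets rose from 0.21 to 0.33. Single arrays ended the calls of HYH (dark unwounded replicate 2 or light unwounded replicate 3), WRKY6 (dark or light unwounded replicate 2), CML38 (dark or light unwounded replicates 2 or 3), EXPA4 (dark unwounded replicates 2 or 3 or light unwounded replicates 1 or 2) and AT2G04400 (any dark unwounded replicate or light unwounded replicates 1 or 2), with limma adjusted p between 0.0513 and 0.155.

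In wounded rosettes, TBL26 was again higher in the light, by 34.5-fold (5.11 ± 0.55). So was AT2G27420, by 4.39 ± 0.77 (at least 14.4-fold with the dark level of 3.46 set to log2 4). AT3G44450 (BIC2, 3.93), BSMT1, a methyltransferase of benzoic and salicylic acid (3.86), AT2G44940 (3.78), AT2G15020 (3.71), AT5G42760 (3.35) and CSLA01, of the glucomannan synthase family (3.09), made up the rest of the 8 largest named rises. AT5G39580, a peroxidase, was lower in the light by a log2 change of -5.11 ± 0.90, at 3.51 ± 1.19 against 8.62 ± 0.74 in the dark (SD, n = 3), or at least 24.6-fold lower with the light level set to log2 4. GAT1_2.1, of the glutamine amidotransferase class, was lower by -4.15 ± 0.78 (at least 4.32-fold on the same footing), with values near the low end of the scale in the light (1.96 ± 0.02). AT3G20340 (-3.82), AT2G20670 (-3.62), AT2G31945 (-3.57), SIS (-3.38), AT3G49790 (-3.36) and AT1G54740 (-3.36) were also lower. The arrays did not overlap between light and dark for any of the 16, which is again a condition of the naming rule. The lower mean was below log2 4 for 7 of them.

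In wounded rosettes GI and members of the flavonoid and dehydration lists were higher in the light, and AKINBETA1 and both auxin response genes were lower. GI was 4.88-fold higher (2.29 ± 0.25) and AKINBETA1 6.01-fold lower (-2.59 ± 0.23), while HYH did not pass (1.3 ± 0.44, limma adjusted p = 0.0780). The auxin response genes that fell were WES1 (-2.68 ± 0.38) and GH3.3 (-1.62 ± 0.37), and theirs was the 1 list that camera called (adjusted p = 0.0394), a call lost with an estimated correlation (adjusted p = 0.240) and with the replicate block (adjusted p = 0.0916). Of 3 abscisate and dehydration genes 2 rose, COR15A (1.56 ± 0.14) and COR15B (1.53 ± 0.26), and of 3 flavonoid genes 2 rose, UGT78D1 (1.51 ± 0.28) and UGT78D2 (1.25 ± 0.28), with camera adjusted p of 0.0863 and 0.134. MYC4 rose (1.09 ± 0.27) as 1 of 4 jasmonate response genes. None of the tested rapid wound regulators, WRKY factors, jasmonate catabolism, photosynthesis, chlorophyll, starch and sucrose, glucosinolate, expansin and housekeeping genes passed over all probe sets, while adjusted over the list alone 1 each passed of the WRKY, jasmonate catabolism, starch and sucrose, and glucosinolate lists, and neither OPCL1 nor PYK10 passed. When blocked by replicate, HYH (1.3), JMT (1.32), APL3 (1.43), AT2G04400 (0.88) and OPCL1 (0.85) rose and WRKY22 (-1.1) fell. These 6 are named after their values were seen. GH3.3 lost its call without dark wounded replicate 3 or light wounded replicates 2 or 3, MYC4 without dark wounded replicates 1 or 3 or light wounded replicates 2 or 3, and UGT78D2 without dark wounded replicate 2 or light wounded replicate 3 (limma adjusted p between 0.0568 and 0.0879).

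Light and dark differed in wounded rosettes for 1666 probe sets (limma, Benjamini-Hochberg), 660 higher and 1006 lower in the light, of which 359 and 541 differed at least 2-fold. The arrays were separate for 1662 of these and for 33.5% of all tested probe sets, against 10% by chance. With the replicate block the count was 3922, with 1926 higher and 1996 lower, and held all 1666. Joined with the block, median centring gave 2063 higher and 1880 lower. Alone it gave 720 higher and 940 lower, and quantile normalization gave 699 and 950. The excess of falls was thus kept by both without the block, and was not kept when the block and centring were joined. In the fit with no block the count was 938 without dark wounded replicate 2, 1058 without dark wounded replicate 3 and 958 without light wounded replicate 1.

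The interaction, which asks whether the wound effect differs between light and dark, passed for 2 named genes, both with a larger rise in the light (limma, Benjamini-Hochberg). AT4G29610 rose by 2.24 on wounding in the light and by 0.17 in the dark, an interaction of 2.07 ± 0.20 (limma adjusted p = 0.00486), and the 3 experiments gave 2.07, 1.94 and 2.2. Its mean was 4.66 ± 0.16 in wounded rosettes in the light and between 2.40 and 2.57, near the low end of the scale, in the other groups. AT5G38700 rose by 5.34 in the light and by 3.72 in the dark, an interaction of 1.62 ± 0.20 (limma adjusted p = 0.0368), with 1.82, 1.42 and 1.63 in the 3 experiments. Its intact means were 2.83 in the dark and 2.81 in the light, below log2 4 like those of AT4G29610, so for both genes the sizes are those of the deposited values and a difference between the intact levels could be hidden. The intact SD was 0.04 in the dark and 0.06 in the light for AT4G29610, and 0.02 and 0.03 for AT5G38700. Such small spread below the threshold lowers the SE on which both calls rest. AT4G29610 reached log2 4 only on the wounded light arrays. No member of a fixed list passed for the interaction, and the wound effects of WRKY22 (interaction 2.35 ± 0.50, limma adjusted p = 0.502) and CML38 (1.28 ± 0.74, limma adjusted p = 0.999) were not shown to differ between light and dark. WRKY22 is named here after its value was seen. The brighter WRKY factors that the rule takes, WRKY53 and WRKY6, had interactions of 0.05 ± 0.45 and 0.77 ± 0.52. Camera called the WRKY list for the interaction (adjusted p = 0.00533) with a mean of 1.06 and 1 of 3 members passing when adjusted over the list alone, but not with an estimated correlation (adjusted p = 0.357) or with the replicate block (adjusted p = 0.0561).

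The replicate block called 5 probe sets for the interaction, the same 2 and 3 others. At an unadjusted p under 0.05 there were 477 probe sets without the block and 1102 with it, where chance gives 678. The interaction counts without single arrays lay between 1 and 12, with 12 without dark unwounded replicate 1, 9 without light unwounded replicate 3 and 1 or 2 without any other, and AT5G38700 kept its call without dark unwounded replicate 1, dark wounded replicate 1 or light unwounded replicate 3 and lost it without any of the other arrays (limma adjusted p between 0.0633 and 0.161), with quantile normalization (0.0593), with a trended and robust prior (0.128) and under the stricter brightness filter (0.0536). AT4G29610 was too dim to be tested under that filter and was lost with the trended and robust prior (0.0735), and both were lost with the 25S covariate (both 0.135). Their interactions were then 2.01 and 1.84, and the median SE over all tested probe sets was 0.37 against 0.29.

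Wound effects in light and dark were correlated across the 13567 probe sets (Pearson's r = 0.88, Spearman's rho = 0.70), which are not independent replicates, and the 2 effects share no array. Among the 2156 probe sets called in either, r was 0.93 and the slope of a total least squares line of dark on light was 0.76. Calls in both numbered 716 higher and 244 lower, where independent calls would give 67.2 and 19.7, and 1 probe set was called in opposite directions. Light effects in intact and wounded rosettes were likewise correlated (r = 0.88, rho = 0.86), with 573 higher and 833 lower in both where independence gives 81.2 and 109.5, and none in opposite directions. Among the 3407 called in either, r was 0.92 and the slope of wounded on intact was 0.78.

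**Figure D4:**
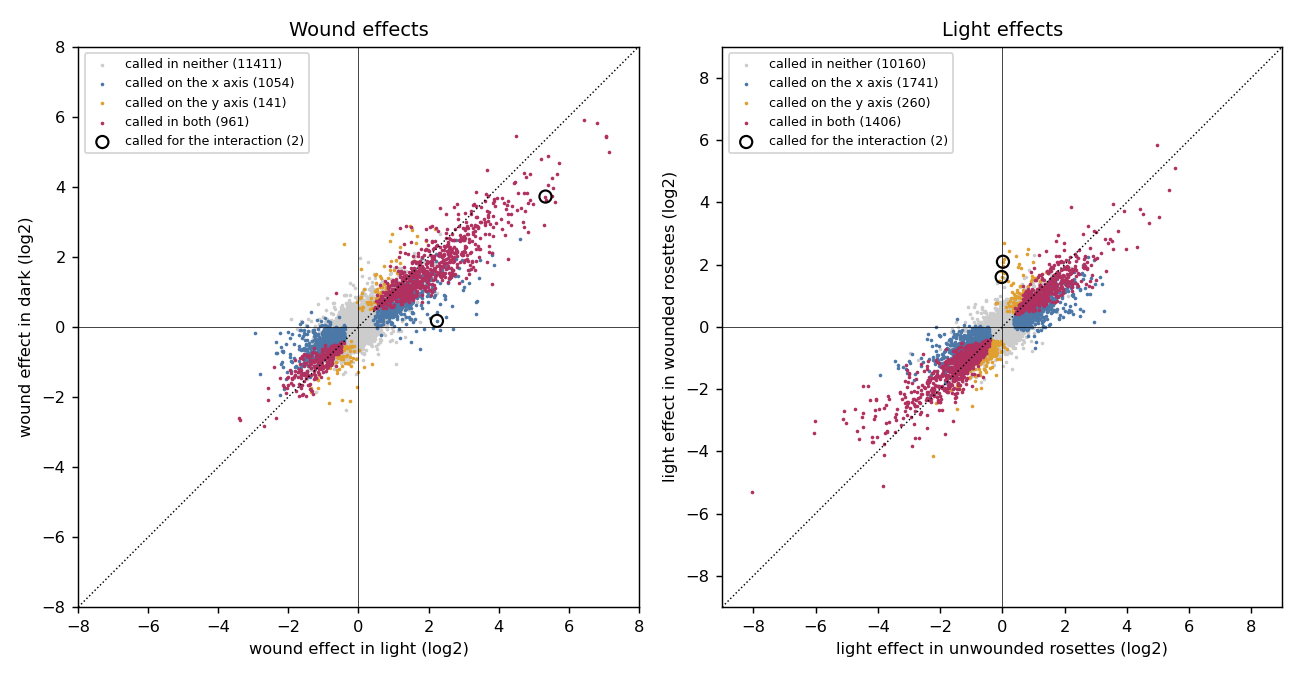
Wound effects in the dark against those in the light (left) and light effects in wounded against those in intact rosettes (right), as log2 changes of 13567 probe sets, with the dotted line where both are equal. Colours mark the 961 and 1406 probe sets called in both, those called in either alone or in neither, and rings mark the 2 called for the interaction.

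Housekeeping and RNA quality measures were compared across the groups. PEX4, a ubiquitin-conjugating enzyme used as a reference gene, had group means between 9.04 and 9.30, and AT2G28390 between 8.11 and 8.47, with no call in any contrast. The 3 prime minus 5 prime difference of the actin control probe sets had group means between 0.58 and 0.78, and that of GAPDH between 0.01 and 0.08. Dark wounded replicate 1 had an actin difference of 1.04 and the other 11 arrays had 0.54 to 0.74. The actin 3 prime control probe set itself stood at 13.61 ± 0.19 and 13.38 ± 0.19 in intact and wounded rosettes in the light and at 13.09 ± 0.16 and 13.06 ± 0.15 in the dark, and that of GAPDH at 13.38 ± 0.12 and 13.28 ± 0.03 against 12.87 ± 0.20 and 12.90 ± 0.16 (SD, n = 3). PYK10, a beta-glucosidase abundant in roots and the 1 tested root marker, had group means between 7.67 and 8.70 and no call.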

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

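The tests with the 25S control value as a covariate and the test on levels in intact rosettes in the dark were chosen after the result was seen. AT4G29610 and AT5G38700 stand here because the wound effect differed between light and dark by limma's test of the interaction. The difference was 2.07 for AT4G29610 (2.24 in the light, 0.17 in the dark, adjusted p = 0.00486) and 1.62 for AT5G38700 (5.34 and 3.72, adjusted p = 0.0368), with the same sign in all 3 experiments for both. Both had intact means below the brightness threshold of log2 4 (2.40 and 2.42 for AT4G29610, 2.83 and 2.81 for AT5G38700), and AT4G29610 stood at 2.57 in wounded rosettes in the dark. These sizes are those of the deposited values, and differences below the threshold could be hidden. The SD of the intact groups was only 0.02 to 0.06, which lowers the SE behind both calls.

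For each comparison of 2 groups, the real split was the 1 of the 10 splits of its 6 arrays with as many calls, and 10 splits are too few for a share under 0.05. The real and the highest other counts were 2015 and 1 for wounding in the light, 1102 and 3 for wounding in the dark, 3147 and 0 for light in intact rosettes, and 1666 and 0 for light in wounded rosettes. Among the 3 other splits that, like the real ones, part all pairs of arrays from the same experiment, the highest count was 0 in each comparison, and the other splits keep some pairs together. Every other split puts the real difference between the groups into the residual. Low counts there follow in part from this, so they do not decide whether chance can be excluded. For the interaction, 4 of 100 random assignments of the 12 arrays to 4 groups, the real one included, gave at least 2 calls. That share is under 0.05, but it does not decide whether chance can be excluded, because regrouping puts the effects of wounding and light into the residual. The median SE was 0.35 to 0.43 in the other assignments against 0.29 in the real one. Another assignment gave 796 calls, which points to a structure of the samples, since regrouping also mixes these effects into the interaction.

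Few probe sets were called for the interaction (2, limma), against 2015 and 1102 for the wound effects. A candidate explanation is spread shared by the 4 arrays of an experiment, which the block removes. With the block the calls went from 2 to 5 and those at an unadjusted p under 0.05 from 477 to 1102, where chance gives 678, as the median SE fell from 0.29 to 0.21. The lower SE with the block shows that such spread was present. Without the block, fewer probe sets reached an unadjusted p under 0.05 than chance gives. Calls of 2 and 5 are too few to decide how far shared spread explains the low count.

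Wound effects tended to be smaller in the dark: over the 1473 probe sets raised by wounding on average over light and dark, the median rise was 1.31 in the light and 1.02 in the dark, the median interaction was 0.29 and 74.7% rose more in the light. By experiment the medians were -0.05, 0.58 and 0.30, so the pattern was absent in replicate 1. The tables argue against 1 unusual array as the cause, since the share with a larger rise in the light stayed between 67.2% (without dark unwounded replicate 2) and 83.0% (without dark unwounded replicate 1). Leaving out 1 array at a time cannot show whether more than 1 array of a group made the pattern together. What stays open is a difference in ribosomal RNA, or in RNA quality as far as the 25S value reads it. The median interaction was 0.20 with that value as a covariate, a change within the spread between experiments and with the high 25S values in the intact dark group. The 3 prime minus 5 prime differences did not set the intact dark group apart. They were 0.64 for actin and 0.01 for GAPDH there, against 0.58 to 0.78 and 0.02 to 0.08 in the other groups. Compression at the ends of the scale was not excluded by the rule set beforehand, which asked for a median above 0 in every experiment. Over the 836 probe sets of the middle range the median was 0.26, and -0.04, 0.53 and 0.28 by experiment. Leaving out the ends of the scale thus changed the pattern little. A biological candidate explanation, higher wound transcripts in intact rosettes in the dark, also stays open: the median light effect over these probe sets in intact rosettes was -0.38 (-0.13 in wounded ones) but 0.05, -0.70 and -0.51 by experiment, and the 0.05 lies within the spread between experiments.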

How the results depend on the processing

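The settings with the 25S value, and those that join the block with another choice, were chosen after the data were seen. Of 208 named results, 108 passed in the main fit. A reversal was counted where the sign changed and the result passed in the main fit or in the other setting. By that rule 0 reversed under the settings each was run in (27 in all, with 175 of the 208 in the fits of 2 groups, 196 under the brightness filter at log2 6 and 117 to 124 without single arrays). Changes of sign in results that passed in neither fit were not counted. With the replicate block 15 came past the threshold and 0 of the 108 were lost, with the 25S covariate 27 were lost, and without replicate 1, 2 or 3 there were 20, 29 and 25 lost. Counts are given in the order wounding in the light, wounding in the dark, light in intact and light in wounded rosettes. The block gave 3699, 2043, 5516 and 3922 calls (5 for the interaction). With median centring added these were 3461, 2042, 5473 and 3943 (interaction 5), with the trended and robust prior added 3798, 2185, 5603 and 4058 (interaction 7), and with the 25S value added 3174, 205, 1137 and 3473 (interaction 0). The 25S covariate alone gave 248 for wounding in the dark, 778 for light in intact rosettes and 0 for the interaction. The intact dark group accounts for 66.3% of the variance of the 25S value. The median called change was 1.32 with the covariate and 1.3 without it for wounding in the dark, and 0.98 both ways for light in intact rosettes. The median SE over all tested probe sets went from 0.21 to 0.30 and 0.33. Fits of 2 groups alone, with fewer arrays, gave 587 for wounding in the dark and 2063 for light in intact rosettes. A 2-fold minimum gave 1240 for wounding in the light, 1523 for light in intact and 900 for light in wounded rosettes, and an adjusted p under 0.01 gave 1120, 521, 1492 and 732 (interaction 1), both being stricter by construction. The interaction count was 0 with the brightness filter at log2 6, 0 with the trended and robust prior and 1 with quantile normalization, and the cause was not tested. Leaving out arrays or experiments gave 789 to 1812, 396 to 1055, 1105 to 3247 and 431 to 1748, and 0 to 12 for the interaction, with 0 called without each experiment (limma). Where that leaves a group with 2 arrays the spread is still pooled over all groups. The correlation of the wound effects, and that of the light effects, was 0.84 to 0.88 without each experiment and 0.90 with the brightness filter at log2 6. Of 65 tests of lists, camera called 9, camera with an estimated correlation 1, camera with the block 8, camera with both 0, fry 19 and fry with the block 33, and fry asks another question, whether the members move 1 way, without a comparison with other genes. The other settings (no brightness filter, median centring and array weights among them) left the 4 counts of wound and light effects within 1.5 times. Signal over background was not measured, and the 9179 dim probe sets were not tested in the main fit.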

Other observations

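The families with a shared symbol stem were chosen after the coverage of the lists was seen, and the members named here after their values were seen. Wounding raised ubiquitin ligases of the plant U-box type: 5 of 8 tested PUB genes rose in the light, PUB22 (log2 change 4.63, limma adjusted p = 3.06e-05), PUB23 (3.48), PUB19 (3.37), PUB24 (2.11) and PUB43 (1.69). The same 5 rose in the dark, by 3.39, 2.55, 3.85, 1.58 and 1.25. The family passed camera in the light (adjusted p = 4.87e-05) and in the dark (adjusted p = 1.66e-04), but not with an estimated correlation (adjusted p = 0.377 and 0.473). Of 6 tested calmodulin-like CML genes, 4 rose in the light, with CML41 (1.58) and CML23 (1.32) beside CML37 and CML38, and 3 rose in the dark, again with calls by camera (adjusted p = 2.77e-04 and 8.21e-04) that were lost with an estimated correlation (adjusted p = 0.377 and 0.473). With the 25S value as a covariate, 3 of the PUB and 1 of the CML genes passed in the dark. Of 14 tested genes that share the symbol stem CYP, 3 fell on wounding in the light, with a mean log2 change of -0.69 where all tested probe sets had a median of -0.15 (camera adjusted p = 0.0367, and adjusted p = 0.711 with an estimated correlation).

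In wounded rosettes 3 of 8 tested ATG genes, all for ATG8 proteins, which build the autophagosome, were lower in the light, ATG8E (-2.75, limma adjusted p = 2.89e-04), ATG8H (-1.29) and ATG8F (-1.10), and camera called the family (adjusted p = 0.00396, and adjusted p = 0.959 with an estimated correlation). In intact rosettes the same 3 were lower (-2.62, -1.26 and -0.83), without a call of the family (camera adjusted p = 0.0697). Of 7 tested SWEET sugar transporters 3 were higher in the light in intact rosettes, SWEET13 (2.73), SWEET1 (1.3) and SWEET17 (0.81), and of 5 beta-tubulin genes 4 were higher (mean 0.53), with camera adjusted p of 0.429 and 0.0689. The intact dark group of these light effects is the one with the high 25S control values (9.62 ± 0.95), and with the 25S value as a covariate 1 of the ATG, 1 of the SWEET and 0 of the tubulin genes passed in intact rosettes, while 3 ATG genes passed in wounded ones. For the interaction camera called the PUB and tubulin families (adjusted p = 0.0470 for both) with 0 members called by limma, calls that were lost with the replicate block (adjusted p = 0.0997 for both) and with an estimated correlation (adjusted p = 0.609 and 0.532).

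With the replicate block, 3 more probe sets passed for the interaction, and they are named here after their values were seen. EXPB1, a beta-expansin, fell by 2.01 on wounding in the light with a change of -0.14 in the dark and an interaction of -1.87 (limma adjusted p = 0.00902 with the block, 0.129 without). AT3G27540 rose by 1.18 in the light and by 2.81 in the dark (interaction -1.63, limma adjusted p = 0.0364 with the block, 0.129 without). A probe set with no gene named rose by 2.34 in the light with a change of 0.65 in the dark (interaction 1.68, limma adjusted p = 0.0217 with the block, 0.147 without). Over the 1455 probe sets lowered by wounding on average, the median interaction was -0.19, and by experiment it was -0.07, -0.32 and -0.14.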
